A study of Mus musculus with 8 samples.

How the data were processed

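Messenger RNA from brain was sequenced for 8 libraries of db/db mice, labelled male, a strain that carries a leptin receptor mutation and develops obesity and type 2 diabetes. Per the labels, 4 libraries came from mice on a ketogenic diet, which is very low in carbohydrate and high in fat, and 4 from mice on a normal diet, called control here. Per the series description, feeding began at 9 weeks and brains were taken whole at 6 months. The labels' protocols state column purification of RNA, 1.3 ug of total RNA per library and a SMARTer kit for messenger RNA.

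The authors deposited a table of raw counts per gene symbol and a table of FPKM values for the same 8 libraries. The genome builds GRCm38 and mm10 are named in the submitters' processing notes. The aligner, the counting program, its use of strand, and the annotation are not given in the sources used here. The deposited counts were whole numbers that summed to between 34450860 and 40233361 per library over 17983 symbols. The deposited FPKM values equalled the count divided by 1 fixed length per gene and by the column total, with a largest relative spread of 1.79e-07 in the implied length between libraries among genes with at least 10 counts in each. They therefore hold no information beyond the counts except the lengths. Of the symbols, 17869 matched RefSeq names of GRCm38.p6 and 17382 matched GENCODE names, and 17728 were protein coding in RefSeq. Mitochondrially encoded genes and nuclear long noncoding RNAs were not analysed here, and the 2 lists fixed for them were not tested.

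The main comparison was ketogenic against control with edgeR 4.0.16 on the deposited counts, with trimmed mean of M values (TMM) factors, edgeR's filter on low counts and its quasi-likelihood F test. The design held an intercept and the diet. The filter kept 14895 genes and left out 3088. P-values were adjusted by the Benjamini-Hochberg method and a gene passed at an adjusted p under 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of F. CPM values are edgeR's read counts scaled to a common library size after TMM, given as mean ± SD over 4 libraries. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Adjustment was over the 52 of 57 fixed lists with at least 5 tested members. Camera with an estimated correlation and fry were run as alternatives. Single values per library (total count, detected genes, share of the top 50 genes, hemoglobin CPM, mean log2 CPM of each cell type and region list) were compared by exact two-sided permutation tests over 70 assignments, whose smallest p is 0.0286. These were adjusted together as 25 values.

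The design, the lists and the rule for named genes were fixed before the data were examined. The rule took, in each direction, the 10 genes with the largest change and the 5 with the smallest p among genes past the threshold with a mean CPM of at least 1 and no overlap between the groups. It skipped predicted genes, of which it met 0. It then took the 4 members with the smallest p in each list past the threshold and in the proteasome, ketone body and fatty acid oxidation lists. Last, it took 11 genes fixed by name, of which 10 are reported here: Bdh1, Oxct1, Pdk4, Cpt1a, Angptl4, Slc16a1, Psmb5, Psma1, Psmd1 and Lepr. A gene that falls outside the rule and is still named was chosen after its values were seen. Coordinates are GENCODE release M21 gene bounds on GRCm38, which may differ from the annotation used for counting. Counts are over whole genes, so no exon or UTR is singled out. Genes with near-identical copies (hemoglobin genes, Hspa1a, Zfp965, ribosomal protein genes with pseudogenes) and genes that overlap a neighbour are uncertain, since the counting could split or share their reads.

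Alternatives chosen along with the design were DESeq2 size factors, library size alone, upper quartile factors, no count filter, a mean CPM of at least 1, the DESeq2 1.42.0 Wald test, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a block on the replicate number, other thresholds, and each library left out in turn. A correction added after seeing the data removed from each library a smooth trend (loess, span 0.3) of its deviation from the gene mean on GC content and log2 length, as offsets in the edgeR fit. GC content was known for 98.1% of tested genes. Leaving out ketogenic replicates 3 and 4 together was also added after seeing the data.

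On simulated counts with the means, library sizes and dispersions of these libraries (14895 genes, ketogenic against control), the test recovered 71 of 100 genes changed 1.5-fold and 84 of 100 changed 2-fold. It made 15 calls among unchanged genes, out of 170 calls, and 3 calls when no gene was changed. A proteasome list raised 1.1-fold was recovered with a camera adjusted p of 1.32e-19, with 0 other lists called. In these simulations genes varied independently of each other, which real genes do not. With a simulated GC trend there were 241 calls among unchanged genes, and 8 once the trend was removed. That trend was linear in GC content, without length, and differed more between the groups than the trend in the real libraries. The 241 calls are therefore no estimate of false calls in the real data. The common biological coefficient of variation in the real data was 10.7%. Replicates of 1 group differed by 9.67 to 23.4 in chi-square per degree of freedom, so no library repeated another. The labels list separate samples but do not say how many animals gave each, so p-values measure the spread between these samples. Intervals of counting error are not printed, because the spread between libraries exceeds it.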

Results

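The data were gene counts from 4 control and 4 ketogenic libraries of db/db mouse brain. Total counts were 34450860, 35821627, 35948836 and 38738800 in control replicates 1 to 4. They were 38781988, 40233361, 38576108 and 38163795 in ketogenic replicates 1 to 4. The first principal component of log2 CPM held 22.9% of the variance and the second 19.5%. Ketogenic replicate 3 lay at 34.4 on the first component, and the other ketogenic replicates at 2.90 to 11.2, with the 4 control replicates between -22.7 and -5.94. The only comparison the labels give is diet, and the series description names proteasome activity among its interests.

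Ketogenic and control brains differed in many genes by small amounts. Lower in ketogenic brains were 14 of 19 activity-dependent immediate early genes and 8 of 23 cholesterol synthesis genes. Higher were 40 of 79 ribosomal protein genes, 17 of 72 respiratory chain genes (with 2 lower) and 8 of 33 proteasome genes, as well as Fkbp5 and the glucose transporter gene Slc2a1. These 5 lists passed as lists with a preset correlation between genes, and none did with an estimated correlation (adjusted p = 0.683 for each). Of 14895 tested genes, 971 (6.52%) passed, 491 higher and 480 lower in ketogenic libraries, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The median size among them was 0.32 in log2, or 1.24-fold, and 89 changed by at least 1.5-fold. Of these, 24 changed by at least 2-fold, 13 higher and 11 lower. The 4 control and 4 ketogenic values did not overlap in 13.7% of tested genes, where chance gives 2.86% on average, and in 824 of the 971. Genes vary together, so a single split can lie far from that average, and the share was not counted in other splits. Passing genes numbered 146 without control replicate 1, 205 without control replicate 2, 423 without control replicate 3 and 1900 without control replicate 4. The count was 588 without ketogenic replicate 1, 196 without ketogenic replicate 2, 714 without ketogenic replicate 3 and 537 without ketogenic replicate 4. It was 417 with the GC and length trend removed (201 higher and 216 lower, 357 of them shared with the 971), 90 without ketogenic replicates 3 and 4, 1767 with the DESeq2 Wald test and 64 with limma on unfiltered log2(FPKM + 1).

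Immediate early genes, which neurons transcribe within minutes of activity, were lower in ketogenic brains. Of 19 tested members 14 fell, 0 rose and 5 did not pass, or 15 lower and 1 higher adjusted over the list alone. Fos, a subunit of the AP-1 transcription factor, went from 60.8 ± 7.28 CPM in control to 29.5 ± 3.38 CPM in ketogenic libraries (SD, n = 4 each), a log2 change of -1.04 ± 0.09 (SE, edgeR adjusted p = 8.34e-05). Egr1, a zinc-finger transcription factor, went from 579 ± 98.9 to 325 ± 32.1 CPM, a log2 change of -0.83 ± 0.10. The orphan nuclear receptor genes Nr4a1 and Nr4a3 were 1.75-fold and 1.69-fold lower, and Egr2 was 2.13-fold lower. The groups did not overlap for any of these 5 genes, and all 5 passed with each library left out in turn. Without control replicate 2 the number of members lower was 9, and with limma on unfiltered log2(FPKM + 1) it was 7. Without control replicate 4 there was 1 member higher. The list's median log2 change was -0.57, with a camera adjusted p of 1.9e-14. The adjusted p was 0.683 with an estimated correlation. The mean log2 CPM of neuron markers was 0.07 lower in ketogenic libraries, at 8.41 ± 0.03 against 8.48 ± 0.04 (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.238).

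**Figure D1:**
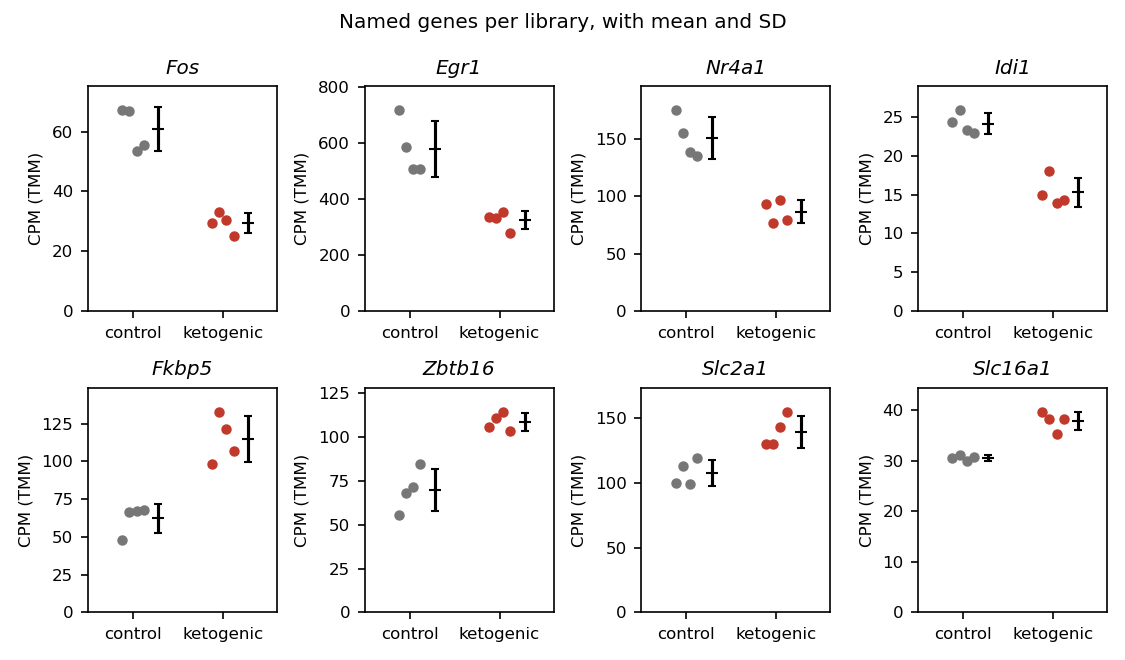
CPM after TMM scaling of 8 genes in each control (grey) and ketogenic (red) library, with the group mean and SD as black bars. Fos, Egr1, Nr4a1 and Idi1 lie lower in all 4 ketogenic libraries, and Fkbp5, Zbtb16, Slc2a1 and Slc16a1 lie higher in all 4.

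Subunit genes of the proteasome, the protease that degrades ubiquitin-tagged proteins, were higher in ketogenic brains by small amounts. Of 33 subunits 8 rose, 0 fell and 25 did not pass, and 16 rose adjusted over the list alone. Psmb4, a core particle subunit, went from 74.3 ± 5.17 to 95.3 ± 7.84 CPM, a log2 change of 0.36 ± 0.07 (SE, edgeR adjusted p = 0.0112). Psmd6 and Psmc2, of the regulatory particle, were 1.24-fold and 1.20-fold higher, and Psmb5, a catalytic core subunit, 1.24-fold higher. Psma1 had a log2 change of 0.21 ± 0.06 (adjusted p = 0.0515) and Psmd1 of 0.08 ± 0.05 (adjusted p = 0.392), neither past the threshold. Psmb4 passed with each library left out in turn. The Psmd6 call was lost without control replicate 1 or 2, the Psmc2 call also without ketogenic replicate 2, and the Psmb5 call without any of control replicates 1 to 3 or ketogenic replicates 1 to 3, with adjusted p of up to 0.0653, 0.0879 and 0.103. The Psmb5 call was also lost with the GC and length trend removed (0.127). The list's median was 0.13, with a camera adjusted p of 1.03e-07, and 0.683 with an estimated correlation. The number of subunits past the threshold was 1 without control replicate 1 or 2, 2 without ketogenic replicate 2, 3 without control replicate 3 or ketogenic replicate 1 or 3, and 4 with the GC and length trend removed. It was 10 without control replicate 4 and 6 without ketogenic replicate 4. It was 0 without ketogenic replicates 3 and 4 together, where the camera adjusted p was 1.3e-05, and 0 with limma on unfiltered log2(FPKM + 1). It was 13 with the DESeq2 Wald test.

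**Figure D2:**
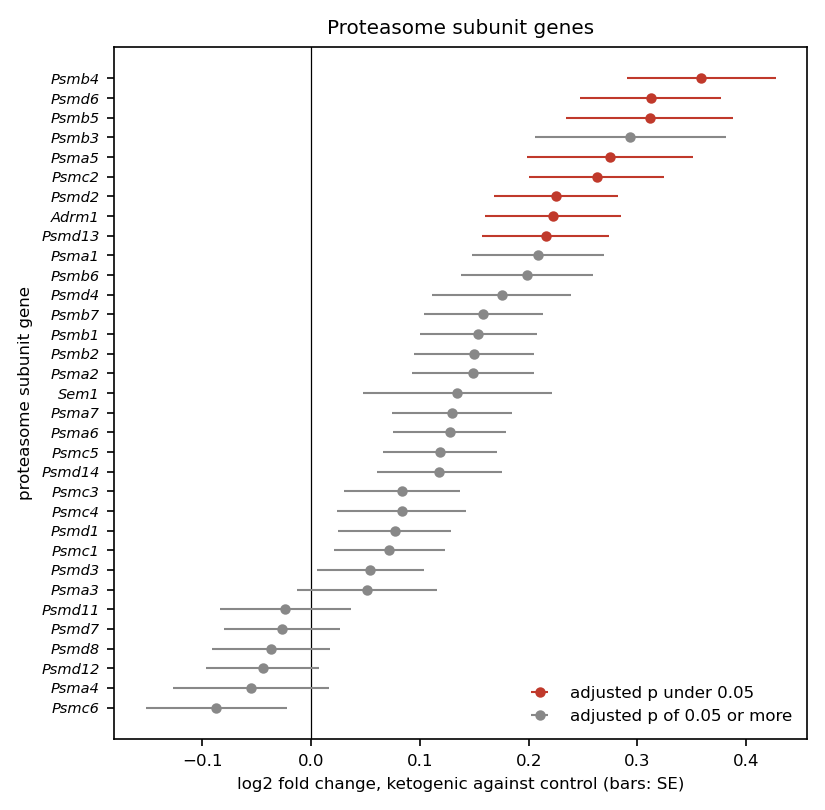
The log2 fold change of ketogenic against control libraries for 33 proteasome subunit genes, with bars of 1 SE. The 8 genes past the adjusted p threshold (red) lie right of 0, and Psmb4 lies farthest right at 0.36.

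The other ubiquitin and proteasome genes did not pass as lists. Activators, immunoproteasome subunits and assembly factors had 2 of 18 members higher (Psme2 and Psmd9, named after their values were seen; camera adjusted p = 0.122). Ubiquitin-activating and ubiquitin-conjugating enzymes had 3 of 34 lower (Ube2d1, Ube2d3 and Ube2l3, likewise named afterwards; camera adjusted p = 0.0615). With the GC and length trend removed 1 of the 18 was higher, Psmd9, and 1 of the 34 lower, Ube2d1, with camera adjusted p of 0.288 and 0.36.

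Cytosolic ribosomal protein genes were higher in ketogenic brains, with 40 of 79 past the threshold, 0 lower, and 53 higher adjusted over the list alone. Rps2 went from 81.2 ± 9.61 to 114 ± 10.1 CPM, a log2 change of 0.49 ± 0.08 (SE, edgeR adjusted p = 0.00709). Rpl18 and Rps16 were 1.30-fold and 1.34-fold higher. The list's median was 0.24 (camera adjusted p = 1.52e-23, and 0.683 with an estimated correlation). The number of members higher was 13 without control replicate 1, control replicate 2 or ketogenic replicate 2, 22 with the GC and length trend removed, 8 without ketogenic replicates 3 and 4 together, and 3 with limma on unfiltered log2(FPKM + 1). There was 1 member lower with the trend removed (Rps26, named after its values were seen) and 1 without control replicate 4. These members are short, with a median length of 795 bases, and short genes were higher in general: the decile of the shortest genes had a median log2 change of 0.08.

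Nuclear genes of the respiratory chain and ATP synthase were also higher, with 17 of 72 past the threshold and 2 lower, Cycs and Atp5pb, named after their values were seen. Adjusted over the list alone the counts were 38 and 4. Atp5g3, of the ATP synthase ring, went from 98.4 ± 2.14 to 127 ± 7.45 CPM, and Atp5l from 63.5 ± 6.77 to 87 ± 6.38 CPM. Ndufv1 and Ndufa7, of complex I, were 1.22-fold and 1.26-fold higher. The list's median was 0.15 (camera adjusted p = 1.03e-11, and 0.683 with an estimated correlation). The higher members were 2 without control replicate 1, 2 without control replicate 2, 3 without ketogenic replicate 2, 2 without ketogenic replicates 3 and 4 together, and 6 with the GC and length trend removed. They were 1 with limma on unfiltered log2(FPKM + 1) and 27 with the DESeq2 Wald test. The lower members were 4 without control replicate 4, 1 without ketogenic replicate 3 and 0 without any other single library. Without control replicate 1 or 2 neither complex I gene passed, and Ndufa7 also failed without ketogenic replicate 2 (adjusted p of up to 0.0506 for Ndufv1 and 0.0617 for Ndufa7). With the trend removed 0 members were lower, the median was 0.09, and both complex I calls were lost (0.0502 and 0.0771). Of 24 pyruvate dehydrogenase and citric acid cycle genes 5 rose and 0 fell, and 5 rose adjusted over the list alone. Idh2 was 1.29-fold, Mdh1 1.19-fold, Sdhd 1.20-fold and Sdhb 1.18-fold higher. That list's median was 0.07 (camera adjusted p = 0.00499, and 0.683 with an estimated correlation), and 1 member, Idh2, passed without control replicate 1, control replicate 2 or ketogenic replicate 2. Without control replicate 3 there were 3, with 2 lower without control replicate 4, and 0 without ketogenic replicates 3 and 4 together. There were 3 with the GC and length trend removed, when the Sdhb call was lost (0.0728).

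Both main glucose transporter genes of the brain were higher in ketogenic libraries. Slc2a1, of the blood-brain barrier, went from 108 ± 10 to 139 ± 12.1 CPM, a log2 change of 0.37 ± 0.07 (SE, edgeR adjusted p = 0.013). Slc2a3, the neuronal transporter, went from 132 ± 13.4 to 163 ± 2.71 CPM. Of 20 glucose uptake and glycolysis genes 3 rose, these 2 and Pfkl, and 8 rose adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.00145, and 0.711 with an estimated correlation). Without control replicate 1 the count was 0, without control replicate 2 or ketogenic replicate 2 it was 1, and without control replicate 4 it was 9, and without ketogenic replicates 3 and 4 together it was 0. It was 8 with the DESeq2 Wald test. With the GC and length trend removed the median was 0.08 (camera adjusted p = 0.0447) and the Pfkl call was lost (0.131). The Slc2a1 call was lost without control replicate 1 (adjusted p = 0.0612). The Slc2a3 call was lost without control replicate 1 or 2 or ketogenic replicate 2 (up to 0.0658), and the Pfkl call without any of control replicates 1 to 3 or ketogenic replicates 1 to 3 (up to 0.144).

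Ketone body genes moved in both directions and did not pass as a list. Of 10 members 2 rose, 1 fell and 7 did not pass, and adjusted over the list alone 3 rose and 1 fell (median 0.04, camera adjusted p = 0.548). Removal of the GC and length trend left 1 higher and 1 lower. Without control replicate 1 or ketogenic replicate 2 there were 0 higher. The median ran from 0.03 without control replicate 4 to 0.12 without ketogenic replicate 3. Slc16a1, a ketone body and lactate transporter of the endothelium, went from 30.5 ± 0.53 to 37.8 ± 1.82 CPM (edgeR adjusted p = 0.0173), a call lost without control replicate 1 (0.0592) or ketogenic replicate 2 (0.0541). The neuronal transporter gene Slc16a7 went the other way, from 52.1 ± 2.79 to 38 ± 3.57 CPM (adjusted p = 0.00608). Aacs had a log2 change of 0.33 ± 0.11 that did not pass. Bdh1 and Oxct1, which use ketone bodies, had log2 changes of -0.08 ± 0.06 and 0.00 ± 0.05 (adjusted p = 0.415 and 0.983).

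Fatty acid oxidation genes did not pass as a list either (1 of 22 higher, 0 adjusted over the list alone, median 0.04, camera adjusted p = 0.602). The median was -2.85e-05 without ketogenic replicate 4 and 0.06 without ketogenic replicate 3. Acadvl, of very-long-chain acyl-CoA oxidation, was 1.22-fold higher (edgeR adjusted p = 0.0455), a call lost without control replicate 1, 2 or 3 or ketogenic replicate 2, 3 or 4 (up to 0.122), and with the GC and length trend removed (0.1). Acadl, Hadha and Acads had log2 changes of -0.22 ± 0.07, -0.12 ± 0.05 and 0.41 ± 0.18, none past the threshold. Cpt1a, which admits fatty acids to mitochondria, had a log2 change of 0.06 ± 0.09, Pdk4 of 0.04 ± 0.12 and Angptl4 of 0.44 ± 0.27. The leptin receptor gene Lepr was at 2.58 ± 0.35 CPM in control and 2.10 ± 0.82 CPM in ketogenic libraries (adjusted p = 0.558). Genes induced through PPAR alpha had 4 of 16 higher and 1 lower (camera adjusted p = 0.0838), and 1 higher and 0 lower with the GC and length trend removed (0.122).

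Genes of cholesterol synthesis were lower in ketogenic brains, with 8 of 23 past the threshold, 0 higher, and 10 lower adjusted over the list alone. Idi1, an isomerase of the mevalonate pathway, went from 24.2 ± 1.32 to 15.3 ± 1.91 CPM, a log2 change of -0.66 ± 0.09 (SE, edgeR adjusted p = 0.00276). Cyp51, Msmo1 and Insig1 were 1.36-fold, 1.31-fold and 1.32-fold lower. All 4 passed with each library left out in turn. The list's median was -0.19 (camera adjusted p = 1.38e-05, and 0.683 with an estimated correlation). Without ketogenic replicates 3 and 4 together 2 members passed, as many as with limma on unfiltered log2(FPKM + 1). Ketogenic replicate 2 had the highest mean of this list in its group.

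Glucocorticoid-induced genes had 6 of 18 members higher and 2 lower, and 8 higher and 2 lower adjusted over the list alone. Fkbp5, a co-chaperone of the glucocorticoid receptor, went from 62.4 ± 9.61 to 115 ± 15.4 CPM, a log2 change of 0.88 ± 0.11 (SE, edgeR adjusted p = 0.000819). Zbtb16 was 1.55-fold and the lipid droplet gene Plin4 2.21-fold higher. Dusp1, which is also an immediate early gene, was 1.51-fold lower, and Per1, a clock gene named after its values were seen, had a log2 change of -0.32. The list's median was 0.15 (camera adjusted p = 0.0162, and 0.683 with an estimated correlation). Its camera call was lost without ketogenic replicate 4 (adjusted p = 0.112), without ketogenic replicates 3 and 4 together (0.197) and with limma on log2(FPKM + 1) (0.0903). Without ketogenic replicate 2 the median was 0.24. The Plin4 call was lost without control replicate 1 or 2 or ketogenic replicate 2 (up to 0.0758). Members past the threshold were 2 higher and 1 lower without control replicate 1, ketogenic replicate 2, or ketogenic replicates 3 and 4 together, and 3 higher and 1 lower without control replicate 2.

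Heat shock genes had 2 of 18 members lower, Bag3 and Stip1, 0 higher, and 3 lower adjusted over the list alone (median -0.08, camera adjusted p = 0.027, and 0.824 with an estimated correlation). Bag3, a co-chaperone, went from 17.1 ± 1.90 to 12.4 ± 1.04 CPM. Hsp90aa1 and Hspa1a had log2 changes of -0.15 ± 0.05 and -0.48 ± 0.22 that did not pass. The camera call was lost without control replicate 4 (median -0.02, adjusted p = 0.615), ketogenic replicate 1 (0.0781) or ketogenic replicate 2 (0.0632). The Bag3 call was lost without control replicate 1 (0.0728), and the Stip1 call without control replicate 1 or ketogenic replicate 2 (up to 0.0896).

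**Figure D3:**
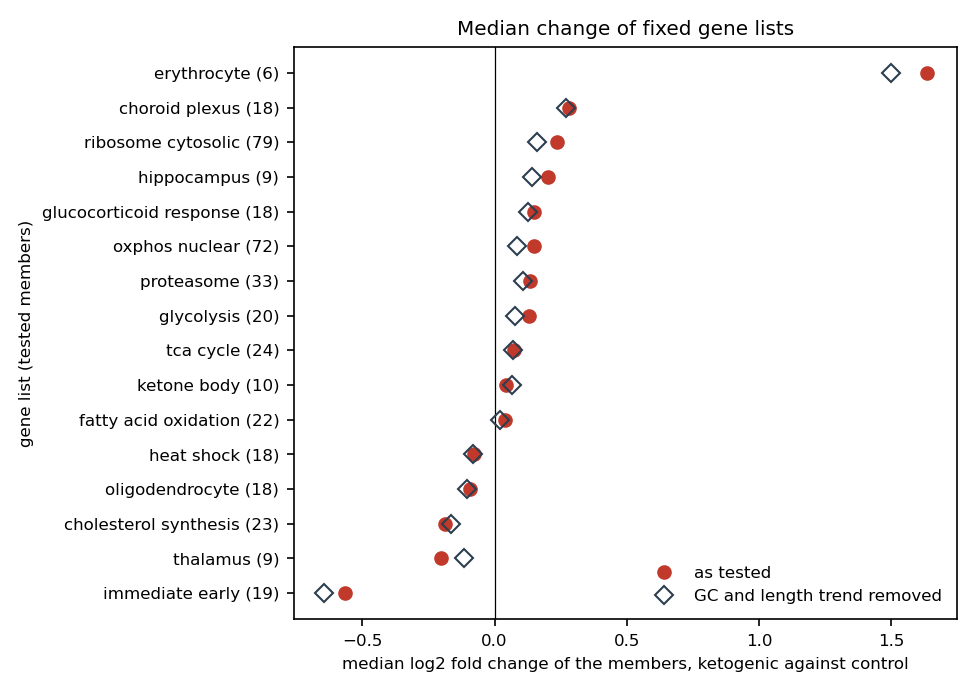
Median log2 fold change, ketogenic against control, of the members of the 14 lists past the camera threshold and of the ketone body and fatty acid oxidation lists, with the number of tested members in parentheses. Red points are as tested and open diamonds have the GC and length trend removed; immediate early genes lie at -0.57 and -0.65, and the proteasome list at 0.13 and 0.11.

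Among genes with the largest changes, Cyp2e1, a cytochrome P450, went from 1.80 ± 0.21 to 0.49 ± 0.24 CPM, a log2 change of -1.88 ± 0.39 (SE, edgeR adjusted p = 0.0171). The urea cycle gene Cps1 and the zinc-finger gene Zfp965 had changes of -1.93 ± 0.50 and -1.62 ± 0.44 at similarly low levels. Ccn1, a matricellular protein gene, was 2.14-fold lower, and Bcl6b, Micall2, Apobec3 and Egfl6 were 1.90-fold to 2.04-fold lower. Higher genes included Rtp1, Fmo2, Pabpn1 and Alox15, by 1.89-fold to 2.27-fold, and Fbxw23, with a log2 change of 1.32 ± 0.37. Ccn1 passed with each library left out in turn. The Cyp2e1 call was lost without control replicate 1 or 2 (up to 0.0578), and the calls of the other 11 genes so far in this paragraph were each lost without control replicates 1 and 2, in separate fits, and without others. Removal of the GC and length trend ended the calls of Cps1, Zfp965, Bcl6b, Micall2, Egfl6, Fbxw23, Pabpn1 and Alox15, with adjusted p of 0.0527 to 0.0747. At higher levels and smaller p, Aqp4, the astrocyte water channel, went from 130 ± 4.77 to 89.6 ± 9.22 CPM (adjusted p = 0.00142). Slc38a2, an amino acid transporter, went from 169 ± 9.60 to 239 ± 19.7 CPM (adjusted p = 0.00142). Gpt2, Rabac1 and Sgsm1 were 1.35-fold, 1.33-fold and 1.32-fold higher. These 5 passed with each library left out in turn.

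Fos lies on chromosome 12 at 85473890 to 85477273 and Egr1 on chromosome 18 at 34859823 to 34864984 (GRCm38). Fkbp5 lies on chromosome 17 at 28399094 to 28517527, Idi1 on chromosome 13 at 8885501 to 8892451, and Psmb4 on chromosome 3 at 94884093 to 94886961. Slc2a1 lies on chromosome 4 at 119108711 to 119137983 and Slc16a7 on chromosome 10 at 125219270 to 125389465.

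Markers of blood differed between the groups. Hemoglobin genes summed to 32.8 ± 15.2 CPM in control and 88.9 ± 19.0 CPM in ketogenic libraries, higher in each of the 4 (exact permutation p = 0.0286, adjusted p = 0.238 over 25 values). Of 6 erythroid genes 4 rose, Alas2, Hba-a1, Hbb-bs and Hbb-bt, by 2.66-fold to 3.38-fold, and 6 rose adjusted over the list alone (camera adjusted p = 8.48e-06, and 0.683 with an estimated correlation). Without control replicate 1 neither Alas2 nor Hbb-bt passed, and without control replicate 2 Alas2 did not. Without ketogenic replicates 3 and 4 together 1 erythroid gene passed, and 0 with limma on unfiltered log2(FPKM + 1). Choroid plexus genes had a median of 0.28 with 1 of 18 higher, Ecrg4, and 2 adjusted over the list alone (camera adjusted p = 0.0102, and 0.824 with an estimated correlation). Ttr, the choroid plexus carrier of thyroid hormone, was at 833 ± 216 and 1141 ± 124 CPM, and it, Trpv4 and Clic6 did not pass. The choroid plexus call was lost without control replicate 2 (median 0.16, adjusted p = 0.268), and the Ecrg4 call without any of control replicates 1 to 3 or ketogenic replicates 2 to 4 (up to 0.0948). The 4 Y-linked genes of the table had 27 counts over all 8 libraries, which are labelled male.

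The list calls of region and myelin markers were each lost when some single libraries were left out. The thalamus list had a median of -0.20 with 0 of 9 members past the threshold and 4 lower adjusted over the list alone (camera adjusted p = 0.02, and 0.824 with an estimated correlation). Its adjusted p was 0.543 without ketogenic replicate 3 and 0.138 without ketogenic replicates 3 and 4 together, and the median was -0.12 with the GC and length trend removed. Tnnt1, Rora, Lef1 and Ramp3 had log2 changes of -0.48 to -0.20, none past the threshold. Hippocampus markers had a median of 0.20 with 2 of 9 higher, Wfs1 and Fibcd1, and 5 adjusted over the list alone (camera adjusted p = 0.0282, and 0.683 with an estimated correlation). Dsp and Spink8 did not pass. That call was lost without control replicate 4 (0.135), without ketogenic replicate 4 (0.134), and with the GC and length trend removed (0.0561), when 0 members passed. Neither gene passed without control replicate 1 or 3 or ketogenic replicate 2 or 4. Oligodendrocyte markers had a median of -0.09 with 3 of 18 lower, Sox10, Ermn and Opalin, and 4 adjusted over the list alone (camera adjusted p = 0.0282, and 0.824 with an estimated correlation). Tspan2 did not pass. That call was lost without control replicate 2 (0.0669), ketogenic replicate 1 (0.0781), ketogenic replicate 2 (0.102) or ketogenic replicate 3 (0.281), and with limma on log2(FPKM + 1) (0.0576). The median was -0.05, -0.06 and -0.04 without ketogenic replicates 1, 2 and 3. Without ketogenic replicate 4 it was -0.23 (camera adjusted p = 4.14e-07). None of the 3 genes passed without control replicate 1 or ketogenic replicate 2. The calls of Ermn (0.179) and Opalin (0.0675) were lost with the GC and length trend removed.

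In all, 14 of 52 lists passed with camera at its preset correlation, 9 higher and 5 lower, and 0 passed with an estimated correlation, where 2 lists had an unadjusted p under 0.05. With fry, which asks whether a list's genes move on balance 1 way, 0 passed and 15 had an unadjusted p under 0.05. With limma on unfiltered log2(FPKM + 1), 0 members passed in the glycolysis, citric acid cycle, choroid plexus, thalamus, heat shock, hippocampus, oligodendrocyte, ketone body and fatty acid oxidation lists, and 1 higher and 1 lower in the glucocorticoid list. The other 38 lists had camera adjusted p from 0.0615 to 0.984. Total counts did not differ past the threshold (exact permutation p = 0.0857), nor did the numbers of detected genes (16542 ± 69.5 against 16593 ± 151, exact permutation p = 0.571).

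**Figure D4:**
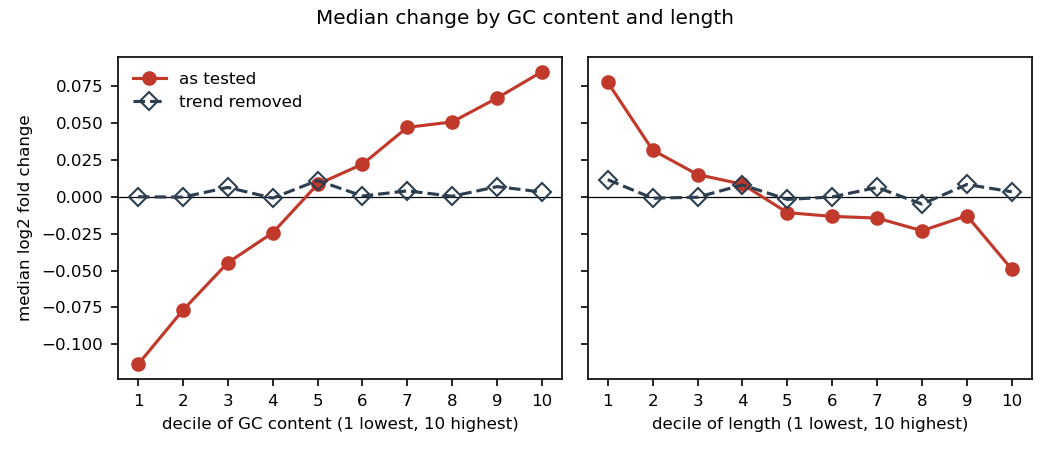
Median log2 fold change of tested genes, ketogenic against control, in deciles of GC content (left) and length (right), as tested (red) and with the trend removed (open diamonds). As tested, the median runs from -0.11 in the decile of lowest GC content to 0.08 in the highest.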

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

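Of 294 groups of 4 libraries tested over the values reported (named genes, gene lists and composition values), 12 (4.08%) held a library far from the other 3, where chance gives about 1 in 20. No explanation was tested for them.

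In list means of log2 CPM, the astrocyte markers were at 7.18 in ketogenic replicate 4 and at 7.07 to 7.08 in the other ketogenic libraries. The choroid plexus markers were at 3.09 in control replicate 2 against 3.61 to 3.71. The respiratory chain list was at 6.43 in control replicate 3 against 6.35 in the others. The cholesterol synthesis list was at 5.58 in ketogenic replicate 2 against at most 5.42 in the others.

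In control replicate 2, Bcl6b was at 3.64 CPM against 1.89 to 2.18, Cps1 at 2.11 against 1.43 to 1.54, and Ecrg4 at 4.17 against 5.76 to 5.99. In control replicate 1, Ermn was at 99.9 CPM against 91.2 to 92.0, Fkbp5 at 48.0 against 66.6 to 68.0, and Rabac1 at 61.1 against 66.1 to 66.2. Rtp1 was at 4.43 CPM in control replicate 4 against 3.14 to 3.17, and Hspa1a at 11.9 CPM in ketogenic replicate 3 against 8.96 to 9.44.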

How the results depend on the processing

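Removal of the GC and length trend, and of ketogenic replicates 3 and 4 together, was chosen after seeing the data, and the other alternatives were set out beforehand. The 971 calls (491 higher, 480 lower) stayed within 1.5 times under DESeq2 size factors, library size alone, upper quartile factors, no count filter, a mean CPM of at least 1 and limma-voom (869 to 1076), and 0 of the 971 changed sign in any refit. The count was 1767 (897 higher, 870 lower) with the DESeq2 Wald test, 417 (201, 216) with the trend removed and 90 (39, 51) without ketogenic replicates 3 and 4. Limma on FPKM gave 766 (453, 313) with a pseudocount of 1 and 735 (436, 299) with 0.1, or 59.1% and 59.3% higher against 50.6%, and with a pseudocount of 1 and no filter it gave 64 (35, 29). A fold of at least 1.5 left 89 (35, 54), an adjusted p under 0.1 gave 2009 (1011, 998), and an unadjusted p under 0.05 with a 2-fold change gave 95 (53, 42). With single libraries left out the count ran from 146 to 1900, the higher genes from 70 to 938 and the lower from 76 to 962. Fewer libraries lower the power, but 1900 calls came without control replicate 4, and the cause of these moves was not tested.

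With the replicate number as a block the count was 1528 (746 higher, 782 lower) and 14 lists passed. Same-numbered samples correlated at 0.02 to 0.08 in their deviations from the group means, and 4 of 8 samples correlated best with their own number. Each correlation lay under the 0.1 fixed beforehand for a pairing, so the main design held no block. A weak pairing is not excluded by this.

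Lists were tested with other count scalings and filters, the block, left-out libraries, the trend removed and FPKM with a pseudocount of 1 after filtering, and not with DESeq2, limma-voom or the other FPKM settings. Their count stayed between 12 and 18 except with an estimated correlation and with fry, both 0. The proteasome list's adjusted p was then 0.683 and 0.0821, and it passed in the other list tests run. The ketone body and fatty acid oxidation lists passed in none of the list tests run. Of 14 lists, 8 passed with each single library left out. Of 66 named genes past the threshold, 29 passed in all 8 such fits and all 66 kept their sign under every alternative run. Reversals were limited to genes near 0 that never passed: with single libraries left out Cpt1a ran from -0.0087 to 0.117, Oxct1 from -0.018 to 0.0316 and Pdk4 from -0.071 to 0.145. Without ketogenic replicates 3 and 4 together they were at -0.033, -0.0366 and -0.107. The hemoglobin difference was 56.1 CPM, from 48.6 to 63.6 with single libraries left out, and 61.9 CPM on the counts outside the top 50 genes. Depth left 3088 genes with too few counts to test.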

Other observations

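The tests of the GC and length trend on single lists, of neuron and cortex markers, of the Y-linked genes, and of camera p over other splits were chosen after their results had been seen. The counts of other splits for gene and list totals and list medians, and the matched random lists, were set out beforehand.

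Several fixed lists that did not pass as a whole held members that moved in both directions. Of 17 circadian clock genes 4 rose (Per2, Cry1, Cry2 and Tef, log2 changes of 0.37, 0.41, 0.23 and 0.23) and 2 fell (Per1 and Nr1d1, -0.32 and -0.26). The list's camera adjusted p was 0.984. With the GC and length trend removed 0 of the 17 rose and 2 fell. Of 16 astrocyte markers 5 fell, among them Aqp4 (-0.54), the gap junction gene Gja1 (-0.34) and Atp1b2 (-0.34), and Fgfr3 rose (0.33), with a camera adjusted p of 0.0838. With the trend removed 4 fell, the Gja1 call was lost (adjusted p = 0.0513), and the camera adjusted p was 0.0372. Of 19 genes of mitochondrial biogenesis and turnover 4 rose (Polg, Sirt3, Mfn1 and Pink1) and the coactivator gene Ppargc1a fell (-0.25), with a camera adjusted p of 0.548. With the trend removed the calls of Pink1 (adjusted p = 0.125) and Ppargc1a (0.226) were lost, and Ppargc1b fell. All genes in this paragraph except Aqp4 were chosen after their values were seen.

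Region markers varied between libraries. The cerebellar granule cell gene Gabra6 had 0 to 5 counts and the Purkinje cell gene Pcp2 0 to 17 counts per library, though the series description speaks of whole brains. The pituitary hormone genes Gh and Prl had 203 and 47 counts in ketogenic replicate 4, 17 and 3 in ketogenic replicate 2, and 0 in the other 6 libraries. The dopamine transporter gene Slc6a3 had 13 counts in ketogenic replicate 3 and 105 to 665 elsewhere, and the oxytocin gene Oxt 34 there and 149 to 718 elsewhere. Each library's deviation in log2 CPM from the gene mean over all 8 libraries was fitted on GC content and log2 length together. The trend on GC content was negative in all 4 control and positive in all 4 ketogenic libraries. Its sign compares libraries with each other and is not the trend of a library by itself. Its slope per 10 points of GC ran from -0.072 to -0.0073 in control and from 0.027 to 0.069 in ketogenic libraries. The labels name no batch, so a technical difference between the groups cannot be told apart from diet.

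The gene counts set the real grouping of the 8 libraries apart from every other split, and the number of lists did not. A share of 1 in 35 is the smallest possible, so a chance arrangement is not excluded. Every other split mixed the diets, and these counts do not tell diet from another difference between the groups. Of the 35 splits into 4 and 4, only the real 1 gave as many as 971 genes, and the highest other count was 1. With the GC and length trend removed, the real split gave 417, and again 1 of 35 splits reached that, with a highest other count of 1. The 14 lists were reached or exceeded in 19 of 35 splits, with a highest other count of 22.

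The proteasome, ribosomal protein and respiratory chain lists were higher in ketogenic libraries, with medians of 0.13, 0.24 and 0.15. With the GC and length trend removed the medians were 0.11, 0.16 and 0.09 and the camera adjusted p values 3.92e-06, 2.63e-14 and 0.000303, and the medians as tested lay above the central 95% of 10000 random lists matched on GC content, length and expression (upper ends 0.0792, 0.0852 and 0.0838). The trend as fitted thus took up a part of each median and not all of it. Neither test decides whether these properties are the whole cause. Camera at its preset correlation gave p as small in other splits. The matched genes were drawn independently, while members of these lists had estimated correlations of 0.32, 0.63 and 0.25, so the matched range is too narrow. A median as far from 0 came in 1, 2 and 1 of 35 splits (highest others 0.12, 0.24 and 0.12), and a camera p as small in 3, 4 and 4 of 35 (real p 7.89e-09, 2.92e-25 and 5.92e-13, lowest others 2.6e-10, 1.13e-49 and 4.36e-19). By the median, only the real split reached its value for the proteasome and respiratory chain lists, and another split did so for the ribosomal list. A share of 1 in 35 is the smallest possible and was not adjusted over lists. Chance is thus excluded for none of the 3, by the median or by camera p, and an effect of diet stays open as a hypothesis.

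Immediate early genes were lower in ketogenic libraries, with a median of -0.57 (95% bootstrap interval -0.76 to -0.31). With the GC and length trend removed the camera adjusted p was 1.84e-16 and the median -0.65, against that trend as the cause. Neuron markers had a median of -0.08 (interval -0.22 to 0.02) and cortex markers of -0.05 (interval -0.30 to 0.10). These intervals resample genes and leave out the spread between libraries. Mean log2 CPM of neuron markers was 8.41 ± 0.03 in ketogenic and 8.48 ± 0.04 in control libraries, which argues against fewer neurons as the whole cause. Cortex means ran from 6.74 to 7.25 in ketogenic and from 7.02 to 7.19 in control libraries. Ketogenic replicates 1 and 3 had cortex means of 7.09 and 7.25. Their immediate early means, 5.59 and 5.71, lay below the control range of 5.96 to 6.14. For those replicates this argues against less cortex as the whole cause. Immediate early means followed the order of cortex means in ketogenic and not in control libraries, so less cortex stays open as a part of the cause. A median as far from 0 came in 1 of 35 splits, the real one (highest other 0.39). A camera p as small came in 2 of 35 (real p 7.31e-16, lowest other 6.74e-17). A share of 1 in 35 is the smallest possible and was not adjusted over lists, so chance is not excluded. An effect of diet stays open, as do the hour of sampling and the handling before it, which the labels do not give; none of these was tested.

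The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 27 counts in all over the 8 libraries, though the labels give male mice. Exact sharing of reads of at least 100 bases with X-linked copies is argued against. Of each gene's longest transcript, 100% of the 100-base stretches occur in no other gene's transcripts. Shorter stretches and matches with mismatches were not checked, so other sharing stays open. A reference without these genes is argued against by the 27 counts themselves. Female animals under a male label cannot be told apart from other causes: no library had more than 6 Y-linked counts, and the X-inactivation transcript, which would decide, was not analysed here. No biological explanation was tested.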
